A study of Mus musculus with 6 samples.

How the data were processed

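RNA-seq was compared between cultures labelled as endothelial cells from the aortas of female and male wild-type mice. The 6 libraries, 3 per sex, were grouped by the sex in the labels. Per the labels' protocols, the cells grew in F-12 medium with serum, heparin and endothelial growth factors, received no treatment, and gave poly-A selected libraries. The protocol names both a strand-marking and a non-marking way of making the library and does not say which was used. The labels do not say whether the libraries of a sex came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

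The deposited table holds counts, which the authors gave as whole-number read counts per gene and library for 54532 genes, without normalization. Per the submitters' processing notes, HISAT2 2.0.5 and featureCounts 1.5 were used. The genome build and the strand setting of the counting are not given in the sources used here. Of the gene identifiers, 99.9% were found in the GENCODE M21 annotation of GRCm38, and 98.3% of those had the same chromosome, start and end there. Coordinates below are those of the deposited table. Genes that overlap on opposite strands, and genes with near-identical copies, can have lost or gained reads in the counting.

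Library totals ran from 17410996 to 22993574 counts, and 25883 genes had a count in at least 1 library. A count of 0 in a single library allows 0.130 to 0.172 CPM (counts scaled to a common library total), taking 3 counts as the floor. Such floors, and the 95% intervals given for ratios (exact binomial), cover counting error only. No libraries of a sex agreed within sampling noise, since the chi-square per degree of freedom between their counts was 7.82 to 78.4.

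Genes were tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test with robust dispersions, TMM normalization and the filterByExpr filter (minimum count 10). This left 14932 genes. Adjusted p-values are Benjamini-Hochberg values of that test, and a gene was called at an adjusted p under 0.05. TMM factors were 0.969 to 1.02. Fold changes are log2 of female over male. Where a sex had 0 counts, the fold is a lower bound against 3 counts over the 3 libraries of that sex, and where it had 1 to 3 counts the ratio is given with its counting interval. CPM values use TMM-scaled totals.

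There were 37 gene lists, 34 of them outside the sex chromosomes, fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. Lists with at least 5 tested genes (30 lists, sex linked ones apart) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. With an estimated correlation, camera takes its degrees of freedom from the libraries and not from the genes, so it has little power here. Of the list entries, 2 were not found in the table and 2 were matched by a RefSeq synonym. Named genes were, first, the 12 with the largest and the 12 with the smallest log2 fold change among called autosomal genes with a symbol, a mean of at least 10 counts per library and no overlap between the sexes. They were, further, up to 4 members of each list with the smallest p, and the sex linked genes. Genes named outside this rule were chosen after their values were seen. In the Results these are Bgn, Cdh5, Tie1, Cldn5, Robo4, Tal1, Pecam1, Eng, Flt1 and Col1a2, and genes named only as overlapping another. Those under Other observations are said there to be so. Of the genes under the rule, 2 are not reported here.

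The alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom with quality weights, no filter and a stricter one (a mean of at least 50 counts), the replicate number as a block, each library left out in turn, and an adjusted p under 0.01. An offset per library for gene length and GC content was added after the data were seen. On counts simulated for this comparison (14363 genes), the same fit recovered 76% of 100 genes changed 2-fold and 90% of 100 genes changed 4-fold, and 11 of its 177 calls (6.21%) were false. Genes were simulated independently of one another and only 200 were changed, so these rates need not hold for the real libraries. In another simulated set, with only a single list shifted, camera called the shifted list and 1 of 29 others, which shares members with it.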

Results

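Gene expression was measured by poly-A RNA-seq in 3 female and 3 male cultures labelled as mouse aortic endothelial cells, to ask how the sexes differ. The female libraries held 21527195, 17410996 and 22993574 counts and the male libraries 20980254, 22897700 and 18138999. Expression levels below are mean CPM ± SD over 3 libraries per sex, and fold changes are log2 of female over male ± SE from edgeR.

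The sex linked genes followed the labels in all 6 libraries. Xist, the RNA that coats the inactive X chromosome, stood at 1089.5 ± 248 CPM in female and 0.304 ± 0.212 CPM in male libraries (log2 fold change 11.74 ± 0.35, edgeR adjusted p = 1.85e-07). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in every female library and 109 ± 22.5, 58.9 ± 3.96, 39.9 ± 11.5 and 29.9 ± 5.45 CPM in male libraries, at least 2287-, 1237-, 838- and 629-fold lower in female against 3 counts over the group. Zfy1, Zfy2, Usp9y and Sry had 0 counts in all 6 libraries. The summed level of these 8 Y-linked genes was 238 ± 37.8 CPM in male and 0 in female libraries (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give).

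Of other transcripts of the X-inactivation centre, Tsix had 0 counts in all 6 libraries, and Jpx (-0.36 ± 0.36, edgeR adjusted p = 0.561) and Ftx (-0.39 ± 0.16, edgeR adjusted p = 0.123) were not called. Of 12 X-linked genes known to escape inactivation, 2 rose in female, 2 fell and 8 did not pass, with the same counts adjusted over the list alone. Those that rose were 5530601H04Rik (0.93 ± 0.15, edgeR adjusted p = 0.00209) and Pbdc1 (0.81 ± 0.17, edgeR adjusted p = 0.0074). Car5b fell by 2.51 ± 0.20 on the log2 scale (edgeR adjusted p = 1.93e-05) and Shroom4 by 1.16 ± 0.25 (edgeR adjusted p = 0.00948, and 0.0559 without female replicate 3). The demethylase gene Kdm6a had a log2 fold change of 0.48 ± 0.21 (edgeR adjusted p = 0.16), Eif2s3x 0.21 ± 0.15 (0.399), Ddx3x 0.11 ± 0.13 (0.64) and Kdm5c 0.09 ± 0.16 (0.759), none of them called, and the sign of Ddx3x and Kdm5c turned without male replicate 3. X-linked genes other than Xist took 2.70 ± 0.0443% of counts in female and 3.19 ± 0.0596% in male libraries, with no overlap (exact permutation test, two-sided p = 0.1, the smallest possible here). Abundant genes weigh most in such a share, and X-linked Bgn alone stood at 2407 ± 83.3 CPM in female and 4653 ± 485 in male libraries.

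**Figure D1:**
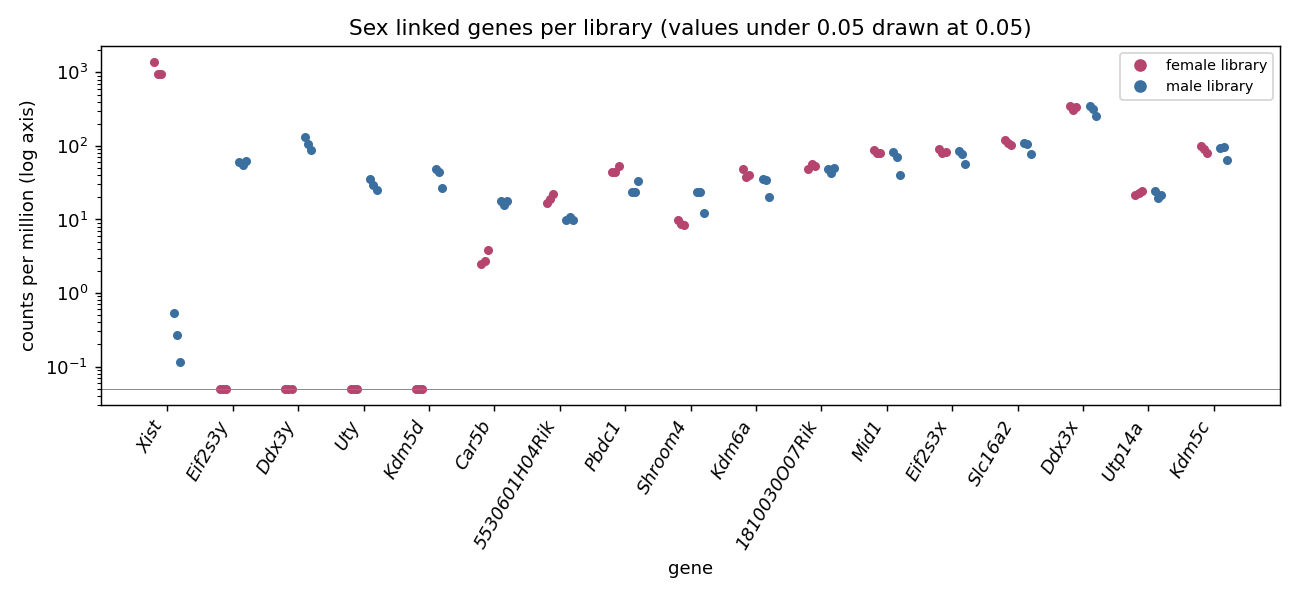
Level of Xist, the Y-linked genes with counts and the escape genes, in CPM on a log axis, with a point per library in 3 female and 3 male libraries. Xist averaged 1089.5 CPM in female libraries, and the 4 Y-linked genes had 0 counts there, drawn at 0.05.

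Most genes of endothelial identity were at or near 0 in both sexes, while fibroblast genes were abundant. Of the 28 genes in the endothelial identity list, 21 stayed under 1 CPM in every library, and Cdh5, Tie1, Cldn5, Robo4 and Tal1 had 0 counts in all 6. Pecam1 (CD31) stood at 0.786 CPM in female and 0.555 CPM in male libraries. Only 9 members were tested, of which 0 rose, 3 fell and 6 did not pass (0 and 4 adjusted over the list alone). Plvap, of the diaphragms of fenestrated endothelium, fell from 113 ± 30.5 CPM in male to 3.53 ± 0.391 in female libraries (edgeR adjusted p = 9.07e-07), Ptprb from 4.55 ± 0.93 to 0.37 ± 0.277 (edgeR adjusted p = 0.000458) and Cd34 from 66.8 ± 0.487 to 32.3 ± 1.24 (edgeR adjusted p = 7.02e-05). The receptors Eng (171 CPM in female, 199 in male) and Flt1 (58.0 and 70.3) were expressed and not called. Camera called the list lower in female (adjusted p = 0.000924), which did not hold with an estimated correlation (adjusted p = 0.175 with an estimated correlation).

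Fibroblast markers differed in both directions, with 6 of 17 tested members higher in female, 6 lower and 5 not passing (6 and 6 adjusted over the list alone). The small proteoglycans Lum (414 ± 12.7 CPM in female, 14.3 ± 2.49 in male, edgeR adjusted p = 1.85e-07) and Dcn (1193 ± 33.0 and 332 ± 22.7, edgeR adjusted p = 3.21e-06) rose, as did Fbln1 (1.36 ± 0.11). Col1a2 (1913 and 1784 CPM) was not called. Camera did not call the list, whose median log2 fold change was 0.10 and mean -0.19.

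**Figure D2:**
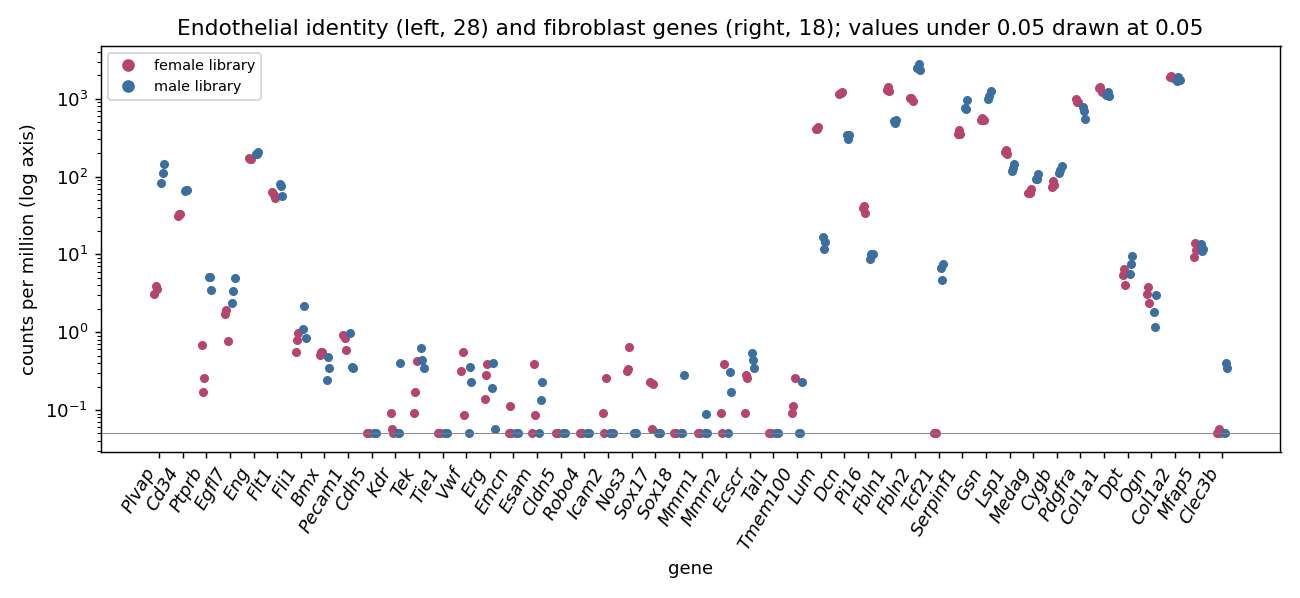
Level of the 28 endothelial identity genes and the 18 fibroblast genes in CPM on a log axis, with a point per library in 3 female and 3 male libraries and values under 0.05 drawn at 0.05. Most endothelial identity genes lie under 1 CPM, with Eng, Flt1, Plvap and Cd34 above it, and most fibroblast genes lie above 10 CPM.

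Between the sexes, 1446 genes were higher and 1287 lower in female of 14932 tested by edgeR. Of these calls, 2635 were autosomal, 90 X-linked (32 higher, 58 lower), 6 Y-linked (1 higher, 5 lower) and 2 elsewhere, and 1537 changed at least 2-fold (806 higher, 731 lower). The sexes did not overlap for 35.9% of the tested genes, where chance gives 10%. Male replicate 3 stood apart from the other male libraries (correlation of log2 CPM with them down to 0.966, against at least 0.983 among female libraries), and without it 2508 genes were higher and 2543 lower. Limma-voom with quality weights called 3305 and 3289.

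The 12 named genes with the lowest fold changes had 0 counts in all 3 female libraries. They included the mesodermal and cardiac transcription factor genes Tbx20 (chromosome 9, 24718138 to 24774303; 36.3 ± 7.91 CPM in male), Gata4 (chromosome 14, 63198922 to 63271692; 34.8 ± 4.71 CPM), Tcf21 (6.28 ± 1.46 CPM) and Tbx5 (5.51 ± 0.957 CPM). Against 3 counts over the group these were at least 762-, 731-, 132- and 116-fold lower in female (edgeR adjusted p = 3.45e-06, 1.42e-06, 4.15e-05 and 3.76e-05). The transcription factor gene Tfap2c (34.1 ± 1.81 CPM in male), the receptor phosphatase gene Ptprz1 (19.8 ± 6.28 CPM) and the prolactin family gene Prl8a9 (13.9 ± 5.48 CPM) were at least 716-, 416- and 293-fold lower. The kinase gene Grk3, the estrogen sulfotransferase gene Sult1e1 and the cholinesterase gene Bche were at least 267-, 238- and 134-fold lower, and Adgrd1 and Slc25a21 at least 107- and 101-fold. Rps16-ps2 overlaps Adgrd1 and Pax9 overlaps Slc25a21 on the opposite strand, and the strand setting of the counting is not known.

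Genes with 0 counts in all 3 male libraries included Adh1, an alcohol dehydrogenase (chromosome 3, 138260991 to 138290698; 12.8 ± 0.798 CPM in female, at least 260-fold higher, edgeR adjusted p = 3.64e-06). The interferon-induced GTPase genes Gbp2b (12.5 ± 4.73 CPM) and Gbp9 (7.02 ± 1.89 CPM) were at least 254- and 142-fold higher (reads shared within their family were not tested). Slitrk6, the BMP family gene Gdf10 and Acss3 were at least 191-, 127- and 63.4-fold higher, and Psma8 and Olfr56 at least 21.5- and 28.4-fold. The span of Olfr56 overlaps Ifi47, Tgtp1 and Tgtp2. Clic5 had 2 counts in male libraries (ratio 747, counting interval 206 to 6171) and Csf2rb, a cytokine receptor subunit, had 3 (ratio 177, 60.3 to 862). The lipid carrier gene Apod (42.2 ± 7.56 CPM in female, 0.178 ± 0.0641 in male) had a log2 fold change of 7.82 ± 0.28 and Crym 7.36 ± 0.30 (edgeR adjusted p = 2.43e-07 and 5.15e-07).

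Interferon response genes rose together, with 25 of 26 tested members higher in female, 0 lower and 1 not passing (25 and 0 adjusted over the list alone). Their median log2 fold change was 2.76. Isg15, a ubiquitin-like protein, went from 1.35 ± 0.412 CPM in male to 28.8 ± 7.24 in female libraries (edgeR adjusted p = 4.96e-06). Oasl2 rose by 3.82 ± 0.23, the transcription factor gene Irf7 by 3.39 ± 0.22 and Rtp4 by 3.62 ± 0.24. Camera called the list (adjusted p = 6.46e-35), which did not hold with an estimated correlation (adjusted p = 0.175 with an estimated correlation). Of antigen presentation genes, 5 of 14 rose and 0 fell (9 and 0 adjusted over the list alone), among them H2-D1 (1.28 ± 0.16) and H2-K1 (0.89 ± 0.14), of a multigene family and so uncertain. Camera called that list too (adjusted p = 0.0018, and adjusted p = 0.405 with an estimated correlation).

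Hox genes, which mark position along the body axis, rose in 12 of 23 tested members and fell in 0 (14 and 1 adjusted over the list alone). Hoxc8 had 17.6 ± 2.95 CPM in female and 0.555 ± 0.16 in male libraries (edgeR adjusted p = 1.79e-06), and Hoxc6, Hoxb9 and Hoxa7 rose by 1.85 ± 0.14, 1.47 ± 0.14 and 1.54 ± 0.15. Camera called the list (adjusted p = 2.83e-06, and adjusted p = 0.175 with an estimated correlation).

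Of extracellular matrix genes, 10 of 52 were higher, 27 lower and 15 did not pass (12 and 27 adjusted over the list alone). Their summed share of counts was not lower in female, at 6.37 ± 0.574% against 5.98 ± 0.811% in male libraries (exact permutation test, two-sided p = 0.7). Col15a1 went from 2328 ± 199 CPM in male to 394 ± 34.3 in female libraries (edgeR adjusted p = 1.2e-06), and Col8a1 and Col6a3 fell by 3.13 ± 0.15 and 2.81 ± 0.16, while Postn rose by 4.09 ± 0.19. Camera called the list lower (adjusted p = 0.00746, 0.0524 without female replicate 3, and adjusted p = 0.58 with an estimated correlation). Mesenchymal transition genes went both ways (6 of 27 higher, 9 lower; 7 and 10 adjusted over the list alone): Col3a1 rose by 1.30 ± 0.12, and Cdh2 (N-cadherin) fell by 1.74 ± 0.11. Camera did not call that list.

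Of angiogenesis and tip cell genes, 8 of 25 rose and 7 fell (8 and 7 adjusted over the list alone). The Tie2 ligand gene Angpt2 went from 1.80 ± 0.346 CPM in male to 52.9 ± 1.63 in female libraries (edgeR adjusted p = 2.25e-07), and Vegfa from 187 ± 7.93 to 649 ± 29.7 (edgeR adjusted p = 2.96e-06), with Nrp2 rising by 2.89 ± 0.20. Camera called the list higher (adjusted p = 0.0195, 0.0666 without male replicate 3, and adjusted p = 0.285 with an estimated correlation). Hypoxia response genes rose in 7 of 21 and fell in 2 (7 and 3 adjusted over the list alone), Egln3 by 2.13 ± 0.11, and camera called them higher (adjusted p = 0.0305, 0.0547 without female replicate 2, and adjusted p = 0.285 with an estimated correlation). Of Notch pathway genes, 1 of 12 rose and 4 fell (1 and 4 adjusted over the list alone), the ligand gene Dll1 by 2.86 ± 0.17 and Notch4 by 2.12 ± 0.19 on the log2 scale (camera adjusted p = 0.0157, and adjusted p = 0.405 with an estimated correlation).

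Immediate early and heat shock genes rose in 9 of 21 members and fell in 1 (10 and 1 adjusted over the list alone). Fos rose by 2.30 ± 0.14 and Egr1 by 1.41 ± 0.11, while Egr2 fell by 1.77 ± 0.12 (camera adjusted p = 0.00138, and adjusted p = 0.285 with an estimated correlation). Lymphatic markers rose in 3 of 6 and fell in 1 (3 and 1 adjusted over the list alone), Pdpn by 1.37 ± 0.12 (camera adjusted p = 0.0219, and adjusted p = 0.285 with an estimated correlation), and fibroblasts express Pdpn too. Of the 10 genes of the lymphatic list, 5 stayed under 1 CPM in every library. No camera call of the 10 held with an estimated correlation. That failure cannot decide the calls, since camera then takes its degrees of freedom from the 6 libraries and has little power. The estimated correlation was -0.0699, -0.0330 and -0.00728 for the endothelial identity, lymphatic and hypoxia lists. These values lie under the preset 0.01, so correlation between genes did not remove those calls. For the other called lists the estimate was 0.0228 to 0.485.

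The remaining lists were not called by camera with all libraries. Vasoactive genes rose in 11 of 27 and fell in 10 (11 and 11 adjusted over the list alone), the endothelin receptor gene Ednrb rising by 5.11 ± 0.27, Thbd (thrombomodulin) by 2.28 ± 0.12 and the prostacyclin synthase gene Ptgis falling by 2.16 ± 0.14. Adhesion and inflammation genes rose in 9 of 25 and fell in 4 (11 and 4 adjusted over the list alone), with Icam1 up by 2.64 ± 0.11 and Il6 down from 37.8 ± 5.67 to 8.96 ± 1.01 CPM. Of TGF-beta and BMP genes 8 of 32 rose, Bmp2 by 2.95 ± 0.10, and 3 fell (10 and 6 adjusted over the list alone), and of Wnt genes 7 of 23 rose and 7 fell (7 and 8), Dkk2 by 2.94 ± 0.15. Sex steroid receptors and targets rose in 1 of 11 and fell in 3 (1 and 3), Fkbp5 by 1.38 ± 0.11. Arterial markers rose in 3 of 12 and fell in 6 (3 and 6; median -0.33, mean 0.14), and venous and capillary markers rose in 4 of 9 and fell in 3 (4 and 3).

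Among other cell types, pericyte markers rose in 1 of 8 and fell in 3 (2 and 3 adjusted over the list alone), Pdgfrb by 1.24 ± 0.13, and smooth muscle markers rose in 4 of 9 and fell in 0 (4 and 2), Itga8 by 1.70 ± 0.22. Lists with under 5 tested genes had no camera test, and most of their genes stayed under 1 CPM in every library. Adipocyte markers fell in 3 of 4 (0 and 3), Plin4 by 3.60 ± 0.18, with 8 of 12 list genes under 1 CPM. Mesothelial markers rose in 2 of 3 (2 and 0), Krt18 by 3.90 ± 0.36, with 9 of 12 under it. Macrophage and leukocyte markers rose in 2 of 4 (2 and 0), Cd14 by 1.22 ± 0.18, with 14 of 18 under it. Neural and glial markers rose in 2 of 4 and fell in 1 (2 and 2), with 8 of 12 under it.

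Metabolic and growth lists differed in their share of called genes. Cell cycle genes rose in 4 of 42, Mcm6 by 0.96 ± 0.14, and fell in 0 (3 and 0 adjusted over the list alone), and cholesterol synthesis genes rose in 4 of 24, Insig1 by 0.83 ± 0.10, and fell in 0 (4 and 0). Glycolysis genes rose in 5 of 22 and fell in 2 (6 and 5; median -0.17, mean 0.04), unfolded protein response genes rose in 4 of 28 and fell in 1 (3 and 1), senescence and p53 targets rose in 5 of 24 and fell in 3 (5 and 4; median -0.03, mean 0.13), and antioxidant genes rose in 1 of 22 and fell in 3 (2 and 5). By edgeR 0 of 55 ribosomal protein genes, 0 of 49 nuclear oxidative phosphorylation genes and 0 of the 12 tested mitochondrial genes of the list were called. At an unadjusted p under 0.05 these were 5, 0 and 0, DESeq2 called 1, 0 and 0, and limma-voom with quality weights 10, 14 and 2. Camera called the ribosomal list lower without male replicate 1 (adjusted p = 0.00070) or male replicate 2 (adjusted p = 0.0492) and not with all libraries (adjusted p = 0.163).

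**Figure D3:**
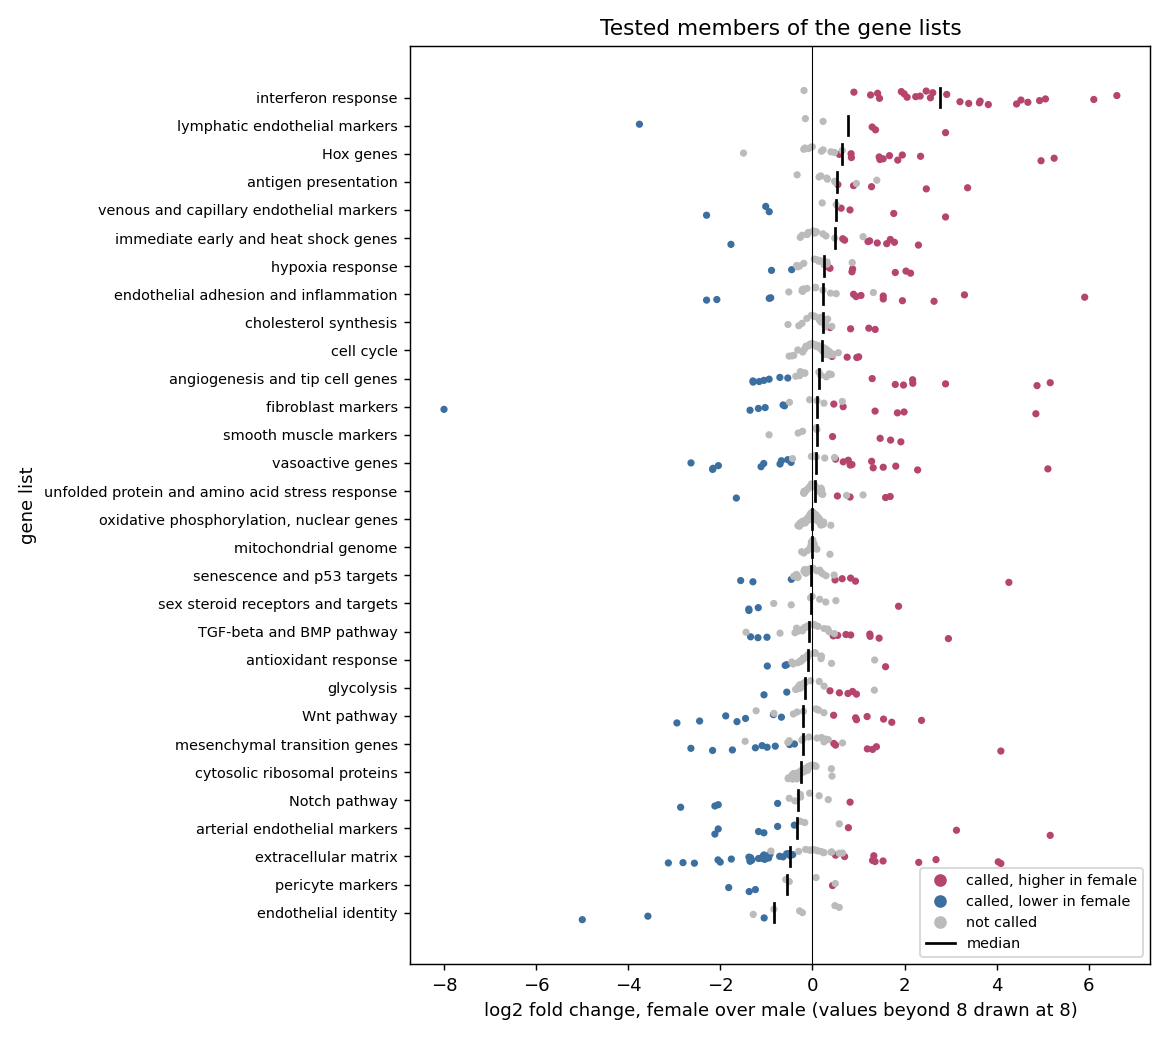
Log2 fold change, female over male, of the tested members of the 30 lists with at least 5 of them, with a point per gene colored by edgeR call and a black bar at each list's median; values beyond 8 are drawn at 8. The interferon list lies farthest to the right, with a median of 2.76.

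Calls were uneven over the chromosomes. On chromosome 1, 164 tested genes were called higher and 46 lower in female, and on chromosome 4, 125 and 46. The median log2 fold change of all tested genes was 0.18 on chromosome 1, 0.15 on chromosome 4, 0.11 on chromosome 5 and 0.10 on chromosome 10. It was -0.13 on the X chromosome, and the lowest autosomes were close to that, with -0.11 on chromosome 19 and -0.10 on chromosome 6.

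**Figure D4:**
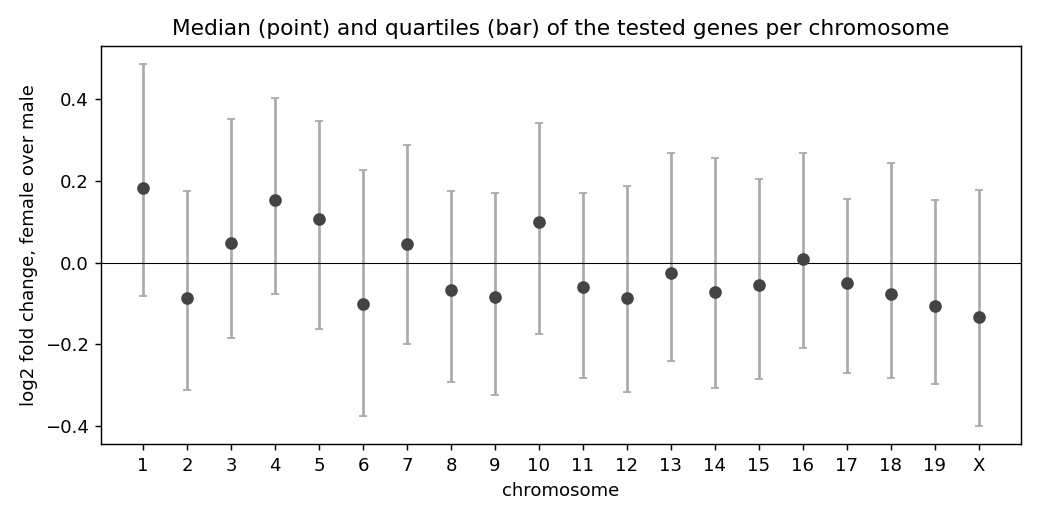
Median log2 fold change, female over male, of the tested genes of each chromosome (points), with bars from the lower to the upper quartile. Chromosomes 1 and 4 have the highest medians, 0.18 and 0.15.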

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

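Of the alternatives, the length and GC offset was chosen after the data were seen. Among the main calls, 98.8% were called again with RLE scaling, 98.9% with DESeq2 and 99.2% without male replicate 3, all of them in the same direction. Limma-voom with quality weights called 3305 genes higher, 3289 lower, 6347 autosomal and 408 list members. At an adjusted p under 0.01 the counts were 900, 835 and 1670 autosomal. With the length and GC offset 1913 genes were higher and 2119 lower, so that fewer were higher than lower. Leaving out each library in turn gave 967 to 2508 genes higher, 903 to 2543 lower and 1798 to 4864 autosomal, with each highest value without male replicate 3. The cause was not tested. Camera called 0 lists with an estimated correlation and fry 20. The X-linked difference as mean log2 CPM against autosomes was -0.22, on another scale than the share. At least a 2-fold change was called for 1108 to 2082 genes.

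Whether the replicate numbers pair the samples was not settled: deviations from the group mean of same-numbered libraries correlated at 0.206, -0.00405 and 0.152. Female replicates 1 and 3 correlated best with the male library of the same number. Female replicate 1 correlated almost as well with male replicate 2 (0.184), and female replicate 2 correlated best with male replicate 3 (0.104). With the replicate number as a block, 1619 genes were higher, 1449 lower, 2943 autosomal and 1567 at least 2-fold, with 272 list members and 10 lists.

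Of the 141 named genes called, 124 were called under every setting that tested them. Some of these, such as Acss3, Olfr56 and Slc25a21, were not tested under the stricter filter. The sign changed for named genes and lists that were not called with all libraries. With limma-voom the log2 fold change was 0.025 for Jpx and -0.054 for Kdm5c. Leaving out each library in turn gave -0.065 to 0.18 for Kdm5c, -0.0047 to 0.21 for Ddx3x, -0.52 to 0.17 for Krt19 and -0.46 to 0.077 for mt-Nd5. The camera direction of oxidative phosphorylation turned with no filter (adjusted p = 0.957) and with the replicate block (0.949), and with fry (0.971). Without each library in turn, the camera adjusted p, with turns of direction, was 0.0474 to 0.915 for oxidative phosphorylation, 0.668 to 0.979 for glycolysis, 0.577 to 0.964 for the mitochondrial genome and 0.00070 to 0.726 for ribosomal proteins. Without male replicate 3, oxidative phosphorylation passed the threshold, as did arterial markers and cholesterol synthesis (adjusted p = 0.0409 for both). Adhesion and inflammation passed it without female replicate 1 (0.0470). With no filter, cholesterol synthesis (0.0306), adhesion and inflammation (0.0347) and ribosomal proteins (0.0462) passed it. Depth limits what can be said of a gene with 0 counts to levels above 0.130 to 0.172 CPM per library.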

Other observations

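The tests and genes below were chosen after the result was seen, except the count of splits for all genes called. Further members of the Ifi200 family, interferon-inducible DNA sensors clustered on chromosome 1, rose in female: all 7 tested did. Ifi207 went from 3.03 ± 0.803 CPM in male to 67.0 ± 1.49 in female libraries (edgeR adjusted p = 5.74e-07), Ifi204 rose by 3.05 and Mndal by 4.15 on the log2 scale. All 7 tested guanylate-binding protein genes rose too, Gbp3 by 3.64 and Gbp2 by 0.90. All 4 tested prolactin family genes, clustered on chromosome 13, fell: Prl2c2 went from 1055 ± 227 CPM in male to 197 ± 27.2 in female libraries (edgeR adjusted p = 1.19e-05), and Prl2c5 fell by 5.69. Reads shared between members of these families were not tested, and single levels are uncertain.

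The genes with the smallest p were Col2a1, cartilage collagen (295 ± 51.7 CPM in male, 0.583 ± 0.0923 in female libraries), and the scavenger receptor gene Scara5 (405 ± 11.8 and 2.49 ± 0.574), both with an edgeR adjusted p = 6.89e-08. Spp1 (osteopontin) and Fn1 (fibronectin) were the most abundant genes, at 27261 and 23724 CPM in female libraries, and neither was called. The Y-linked pseudogene Mid1-ps1 rose in female libraries by 1.40 ± 0.35 (edgeR adjusted p = 0.0194), and reads shared with the X-linked Mid1 were not tested. The mitochondrial ribosomal RNA gene mt-Rnr1, outside the list, fell by 0.68 ± 0.19 (edgeR adjusted p = 0.0314). The mitochondrial genes mt-Co2 and mt-Co3 stood at 24.9 and 21.5 CPM in female libraries beside 8972 for mt-Co1, so their levels are uncertain.

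Endothelial identity genes were near 0 in all libraries. Depth is argued against, since a count of 0 allows at most 0.171 CPM in any library on TMM-scaled totals, and so is loss of reads to genes on the opposite strand, as 9.52% of the 21 near-zero genes overlap one with counts. The median of the fibroblast list, 5 of whose 18 genes another list holds, was at least 115 CPM in every library, with Col1a2 at 1913 CPM in female and 1784 CPM in male libraries. Cells of another type may make up much of the cultures, but endothelial cells that changed in culture would give the same values and these cannot be told apart.

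Genes of chromosomes 1 and 4 were higher together in female. Length and GC content are argued against, as a difference of at least 0.18 in log2 remained with the offset. In 18 of 18 windows of 20 Mb (100%) on these chromosomes the median was above that of the other autosomes. The same held for 8 of 8 windows on chromosome 7, 7 of 7 on chromosome 10 and 7 of 8 on each of chromosomes 3 and 5, so this is not particular to chromosomes 1 and 4. A difference in whole-chromosome copy number between the cultures stays open, as does a sex difference in regulation, which was not tested. These cannot be told apart here.

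Male replicate 3 stood apart from the other male libraries. Its total of 18138999 counts lay within the range of the others, which argues against library size. Gene length and GC content explained 43.6% of the variance across genes of its deviation, between the bounds set for and against them, and 44.9% for male replicate 1, so whether they are the cause cannot be told. The value for male replicate 1 is not independent, since male replicate 3 is part of the mean it was compared with. No biological explanation was tested.

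The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split alone (1 of 10) gave as many genes called (2733), autosomal calls (2635), 2-fold calls (1537) and list members called (252), and the highest of the other splits gave 0 of each by edgeR (26 to 1751 genes at an unadjusted p under 0.05). Every other split mixes the sexes in both groups, so the sex difference adds to the spread within groups there. The 0 calls therefore do not show what a random grouping of alike libraries would give. For lists called by camera, 2 of 10 splits gave as many: the real one called 10 and another, of female replicate 1 with male replicates 1 and 2, also called 10.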
